A study of Mus musculus with 32 samples.

How the data were processed

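Poly(A) RNA from the lungs of C57B/6 mice was sequenced in 32 libraries. Per the labels, RNA was isolated with Trizol and libraries were made with the NEBNext Ultra 2 RNA kit. The deposited raw counts hold whole-number counts per Ensembl gene for 35275 genes, and the deposited normalized expression table holds 35186 of them in TPM. That unit is not named in the header. It was settled from the values: 100% of them equal the count divided by the table's gene length and scaled to the same total in every library, within a tolerance of 1e-06. The other 89 genes are in the count table only. The submitters' notes name FastQC and the genome builds GRCm38 and mm10, while the aligner and the counting program are not given in the sources used here. Of the Ensembl identifiers, 34490 (97.8%) are in GENCODE M21, and of these 99.99% lie on the same chromosome and 79.4% have the same start. In 27 genes the symbol had been turned into a date, so genes were matched by identifier. Gene coordinates printed are those of the deposited count table.

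Each count column was mapped to a library by its label, with 0 columns left unmapped. Groups were those of the labels: 8 groups in 2 experiments, of 3 or 5 libraries each. The replicate numbers show little sign of pairing between groups, as given in the closing section, so no pairing was used in the main comparisons. No 2 libraries of the same group were near-copies of each other, and pairs from different groups were not checked for this.

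The counts of each experiment were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the groups as design (16361 genes in the first experiment and 16874 in the second), scaled by TMM, and fitted with 1 mean per group and a robust quasi-likelihood dispersion shared by the 4 groups. Each comparison used edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Interactions tested the difference of log2 fold changes. CPM values use the TMM-scaled library totals of the experiment. Airway, erythroid, clock, liver and nuclear RNA scores are means of log2 CPM normalised over all 32 libraries; the clock score is the mean of the Per and Dbp arm minus that of the Bmal1 arm, and the nuclear RNA score is the mean of Malat1 and Neat1. Overlaps between comparisons were set beside the product of the called shares. Replicates in all p-values are libraries.

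A total of 67 lists of cell markers and pathways, written before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the lists with at least 4 genes tested. Each was tested again with the correlation estimated from the data. In a list, genes were counted as risen or fallen at an adjusted p under 0.05 over all genes, and again with the adjustment made over the list alone. Sets of 200 autosomal genes with the smallest p between sexes in smoke (male-high and female-high) and between smoke and air in females (smoke-raised and smoke-lowered) were tested in the same way in the second experiment, without adjustment over sets.

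Genes to be named were set by a rule before the data were examined. For both smoke comparisons, sex in smoke and both ovariectomy comparisons, it takes the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 1, groups that do not overlap and a regular gene symbol, with X- and Y-linked genes apart in the sex comparisons. For the other comparisons it takes 4 and 4. It adds up to 4 members with the smallest p of each called list and a fixed panel of 24 genes. The rule gives 240 called genes by comparison, and the tallies of stability in the closing section cover all of them. The genes printed are the largest changes, apart from some that are not reported here, and a choice, made after their values were seen, among the list members and the panel. The 8 genes plotted were also picked after their values were seen.

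Alternatives tried were RLE size factors, no filter on low counts (at least 1 count), a strict filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, all 32 libraries in 1 fit, only the 2 groups compared, limma-trend on log2(TPM + 1), the Wald test of DESeq2 1.42.0, an estimated correlation, sets taken from sex in air or from called genes, and leaving out each library in turn. Added after the data were seen were leaving out the libraries over 100 CPM of the liver gene Alb, and offsets for transcript GC content in a centred and an uncentred form. Other splits of the libraries into groups of the same sizes were fitted in the same way (all of them, or 100 drawn). Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

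The depth of 13790052 to 24497332 counts per library sets the precision together with the 3 or 5 libraries per group. The procedure was tested on simulated data with the depth and spread of each comparison. Counts were drawn for each gene apart, without the correlation between genes of the real data, so false calls hold for independent genes only. Besides a set of genes raised less, whose calls were counted as true, 100 genes were changed 1.5-fold and 100 genes 2-fold. edgeR recovered 38 and 77 of these for smoke in females (5 false among 135 called), 44 and 61 for smoke in males (3 false among 123), 19 and 54 for the interaction of sex and smoke, 32 and 67 for sex in air, and 52 and 74 for sex in smoke. It recovered 45 and 69 for ovariectomy at 3 months, 50 and 61 at 5 months (2 false among 123), and 15 and 51 for the interaction of ovariectomy and time. For change with time it recovered 41 and 60 in sham and 37 and 66 in ovariectomized mice. DESeq2 recovered 44 and 80 for smoke in females (21 false among 162 called) and 52 and 69 for ovariectomy at 5 months (20 false among 151).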

Results

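Gene expression was measured by RNA sequencing of poly(A) RNA from the lungs of C57B/6 mice, in 32 libraries that fall into 8 groups and 2 experiments. In the first experiment, males and females breathed room air (3 libraries per sex) or smoke (5 libraries per sex) for 5 months. In the second experiment all mice were females exposed to smoke after removal of the ovaries (ovariectomy) or a sham operation, and lungs were taken at 3 months (3 sham and 3 ovariectomized) or 5 months (5 sham and 5 ovariectomized). Raw counts were available for 35275 genes. Total counts per library lay between 13790052 and 24497332. By group, in megacounts (M), they ran from 16.8 to 17.1 M in male air, 17.2 to 20.4 M in female air, 13.8 to 20.8 M in male smoke and 13.8 to 19.4 M in female smoke. In the second experiment they ran from 15.2 to 15.8 M in sham and 14.2 to 19.0 M in ovariectomized mice at 3 months, and from 14.2 to 17.9 M and 14.8 to 24.5 M at 5 months. The labels do not state that the libraries of a group come from separate animals, so every p-value below measures the spread between libraries, which can be technical. Levels are in CPM, counts scaled to library size, as mean ± SD over the libraries of a group.

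What prolonged smoke exposure changes in the female lung was asked by comparing 5 smoke with 3 air libraries. The arms of the circadian clock moved in opposite directions. Arntl, which encodes the clock activator Bmal1 (chromosome 7, 113207465 to 113314122), was at 33.5 ± 3.99 CPM in smoke (n = 5) and 11.03 ± 3.19 CPM in air (n = 3), a 3.02-fold rise (log2 fold change 1.60, SE 0.16). Dbp, a transcription factor driven by the clock (chromosome 7, 45705088 to 45710155), fell 6.87-fold, from 77.5 ± 26.9 to 11.3 ± 3.66 CPM. Of the 5 tested genes of the Bmal1 arm, 4 rose (5 adjusted over the list alone), with Npas2 3.37-fold and Nfil3 2.23-fold higher. The arm's median log2 fold change was 1.16 (adjusted p = 9.88e-07, and adjusted p = 0.191 with an estimated correlation). Of the 10 genes of the Per and Dbp arm, 8 fell (10 adjusted over the list alone), among them Tef (1.79-fold), Per3 (2.63-fold), Nr1d2 (2.57-fold) and Per2 (2.68-fold). Its median was −1.14 (adjusted p = 4.80e-11, and 0.111 as adjusted p with an estimated correlation). The labels give no hour of collection.

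Connective tissue and vascular genes were lower in smoke-exposed females. Of 15 extracellular matrix genes 9 fell and 0 rose (11 fell and 1 rose adjusted over the list alone; median log2 fold change −0.50, adjusted p = 1.00e-08, and adjusted p = 0.247 with an estimated correlation). Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), fell 2.37-fold, from 504 ± 18.6 to 213 ± 40.2 CPM. Col1a2 fell 2.16-fold, the type III collagen gene Col3a1 1.90-fold and the type VI collagen gene Col6a1 1.62-fold. Among markers of adventitial fibroblasts, 4 of 9 fell (6 fell and 1 rose adjusted over the list alone; median −0.50, adjusted p = 0.00278, and adjusted p = 0.247 with an estimated correlation), including Pi16 (1.76-fold) and Mfap5 (1.64-fold). Of 8 markers of aerocytes, the capillary cells specialised for gas exchange, 5 fell (6 adjusted over the list alone; median −0.49, adjusted p = 9.40e-06, and adjusted p = 0.240 with an estimated correlation), including the endothelin receptor gene Ednrb (1.40-fold) and Tbx2 (1.45-fold). Of 9 markers of general capillary cells 5 fell and 1 rose, both over all genes and adjusted over the list alone (median −0.53, adjusted p = 0.00345, and adjusted p = 0.309 with an estimated correlation). Cxcl12, which encodes a chemokine, fell 1.45-fold. Of 8 pericyte markers 4 fell (5 adjusted over the list alone; median −0.50, adjusted p = 9.35e-05, and adjusted p = 0.247 with an estimated correlation). Gucy1b3, a subunit of the nitric oxide receptor, fell 1.46-fold.

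Genes of alveolar type 1 cells, which form the gas-exchange surface, rose: 7 of 11 (8 adjusted over the list alone; median log2 fold change 0.53, adjusted p = 2.98e-07, and adjusted p = 0.247 with an estimated correlation). Igfbp2, an insulin-like growth factor binding protein gene used as a marker of these cells, rose 2.05-fold, from 357 ± 27.5 to 731 ± 90.0 CPM. Erythroid genes were also higher, with 7 of 8 risen both over all genes and adjusted over the list alone (median 2.38, adjusted p = 2.30e-10, and adjusted p = 0.214 with an estimated correlation). The alpha globin gene Hba-a2 went from 53.3 ± 11.7 to 310.4 ± 131 CPM, and Alas2, the first enzyme of haem synthesis in red cell precursors, rose 6.86-fold. Of 8 platelet and megakaryocyte genes 3 rose (5 adjusted over the list alone; median 0.90, adjusted p = 2.85e-05, and adjusted p = 0.191 with an estimated correlation), with the platelet chemokine gene Ppbp 3.75-fold higher. Of 11 plasma cell genes 4 rose (6 adjusted over the list alone; median 0.99, adjusted p = 7.28e-04, and adjusted p = 0.247 with an estimated correlation). Igj, the joining chain of secreted antibody, rose 16.4-fold, from 6.57 ± 0.835 to 108 ± 78.8 CPM. Reads of immunoglobulin segments are shared within families, so single segments are uncertain. Lists that follow RNA quality moved too: 4 of 9 mitochondrially encoded genes rose (8 adjusted over the list alone; median 0.45, adjusted p = 1.56e-05, and adjusted p = 0.305 with an estimated correlation) and 3 of 15 cytosolic ribosomal protein genes (9 adjusted over the list alone; median 0.23, adjusted p = 1.33e-04, and adjusted p = 0.413 with an estimated correlation).

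The series concerns dendritic cells and monocytes in the smoke-exposed lung, so their genes are given next. In females, markers of mature migratory dendritic cells were lower, with 3 of 11 fallen, also adjusted over the list alone (median log2 fold change −0.23, adjusted p = 0.00593, and adjusted p = 0.305 with an estimated correlation). The chemokine genes Ccl22 (7.61 ± 1.19 against 14.9 ± 2.67 CPM, 1.95-fold) and Ccl17 (1.90-fold) fell. Both calls ended without female air library 3 (adjusted p = 0.0541 and 0.0953). In males Ccl22 fell 1.79-fold, a call that ended without male air library 3 (adjusted p = 0.0936). Flt3, a growth factor receptor gene of dendritic cells, fell 1.78-fold in females (2.37 ± 0.346 against 4.25 ± 0.131 CPM), a call that ended without any 1 of the 3 air libraries or female smoke library 1 (adjusted p up to 0.0774). Ccr2, the chemokine receptor of classical monocytes, rose 1.38-fold in males (34.7 ± 5.10 against 25.2 ± 3.93 CPM), a call that ended without male air library 2 or 3 or male smoke library 2, 4 or 5 (adjusted p up to 0.204). The B cell chemokine gene Cxcl13 rose 3.51-fold in females and 3.56-fold in males. Its call ended without any female air library or female smoke library 1, 2 or 3 (adjusted p up to 0.197), and without male air library 1 or 3 or male smoke library 1, 2, 4 or 5 (up to 0.150). Ly6c2, a marker of classical monocytes, rose 1.79-fold in females (19.99 ± 3.42 against 11.2 ± 2.28 CPM) and 2.05-fold in males (23.0 ± 3.09 against 11.2 ± 0.760 CPM). The lists of classical monocytes (median 0.52, adjusted p = 0.105 in females, 0.28 and 0.393 in males) and of both types of conventional dendritic cells (adjusted p = 0.354 and 0.333 in females, 0.212 and 0.887 in males) did not pass the test. Mmp12, the macrophage elastase gene, did not pass it in either sex (log2 fold change −0.32, SE 0.25, adjusted p = 0.507 in females and −0.12, SE 0.25, adjusted p = 0.831 in males). Cyp1a1, also of the fixed panel, ran from 4.43 to 8.35 CPM in female smoke and from 7.97 to 15.2 CPM in female air. In males it ran from 7.36 to 18.8 CPM in smoke, and was at 12.0, 9.04 and 172 CPM in air libraries 1, 2 and 3.

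Across all 16361 genes tested, 1259 passed edgeR's quasi-likelihood test in females at a Benjamini-Hochberg adjusted p under 0.05, with 739 higher and 520 lower in smoke, and 197 of them changed at least 2-fold. Among the largest rises of genes whose groups did not overlap were those in Igkv3-2 (256-fold, adjusted p = 0.00728), Igkv4-59 (25.1-fold), Ighg2b (24.8-fold), Apol11b (23.4-fold), Trim10 (17-fold), Igj and Slc4a1 (13.9-fold). Of these, only the call of Igj held without every single library tested. Without female air library 3 the calls of Igkv3-2, Trim10 and Apol11b ended (adjusted p = 0.0502, 0.0505 and 0.0582), and Apol11b also ended without female air library 2. Slc4a1 and Igkv4-59 ended without any 1 of the 3 air libraries (adjusted p up to 0.0869 and 0.154), and Ighg2b without any air library or smoke library 1, 2 or 3 (up to 0.162). Among the largest falls were those in Dbp, Zbtb16 (3.75-fold), Retnla (3.71-fold), Atp2b2 (3.53-fold), Sprr1a (3.39-fold), Hif3a (2.97-fold) and Angptl7 (2.94-fold). Retnla ended without female air library 1 (adjusted p = 0.0686), and Atp2b2 without air library 2 or 3 or smoke library 2 or 4 (up to 0.0954). Zbtb16 and Fkbp5 (1.93-fold) are induced by glucocorticoids, and 5 of 12 such targets fell, also adjusted over the list alone (median −0.37, adjusted p = 2.40e-04, and adjusted p = 0.247 with an estimated correlation). Of the genes tested, 14.5% had groups that did not overlap, where chance gives 3.57%. The count of 1259 dropped to 459 without female air library 3.

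The same question was asked in males with 5 smoke and 3 air libraries, and matrix and clock genes again stood out. Col1a1 fell 3.41-fold, from 765 ± 180.3 to 224 ± 17.6 CPM (log2 fold change −1.77, SE 0.14), Col3a1 2.81-fold and Col1a2 2.73-fold. Of 15 extracellular matrix genes 10 fell and 0 rose (13 fell and 1 rose adjusted over the list alone; median −0.85, adjusted p = 1.54e-12, and adjusted p = 0.138 with an estimated correlation). Tnc, which encodes the matrix protein tenascin-C, fell 4.59-fold, from 29.0 ± 5.76 to 6.27 ± 2.12 CPM. Arntl rose 2.34-fold, from 16.8 ± 3.95 to 39.3 ± 1.83 CPM, and the clock repressor gene Per1 fell 4.12-fold, from 143 ± 23.6 to 34.7 ± 7.68 CPM. Of the Per and Dbp arm 8 of 10 fell (10 adjusted over the list alone; median −1.29, adjusted p = 8.88e-11, and adjusted p = 0.133 with an estimated correlation). Of the Bmal1 arm 4 of 5 rose, also adjusted over the list alone (median 0.98, adjusted p = 4.11e-05, and adjusted p = 0.191 with an estimated correlation).

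Alveolar type 1 markers rose in males in 10 of 11 cases, also adjusted over the list alone (median log2 fold change 0.48, adjusted p = 9.84e-08, and adjusted p = 0.244 with an estimated correlation), with Clic5 1.53-fold and Rtkn2 1.58-fold higher. Of 10 fatty acid synthesis genes 6 rose (9 adjusted over the list alone; median 0.38, adjusted p = 6.27e-06, and adjusted p = 0.237 with an estimated correlation). Scd1, a desaturase that makes monounsaturated fatty acids, rose 2.28-fold, from 1447.9 ± 179 to 3306.4 ± 434 CPM. Of 8 aerocyte markers 6 fell (7 adjusted over the list alone; median −0.57, adjusted p = 6.65e-07, and adjusted p = 0.138 with an estimated correlation), including the carbonic anhydrase gene Car4 (1.51-fold) and Kdr, a receptor of vascular endothelial growth factor (1.52-fold). Of 9 general capillary markers 6 fell (7 adjusted over the list alone; median −0.55, adjusted p = 5.53e-05, and adjusted p = 0.214 with an estimated correlation), with Kit 1.81-fold lower. Of 12 glucocorticoid targets 7 fell (10 adjusted over the list alone; median −0.66, adjusted p = 2.09e-07, and adjusted p = 0.138 with an estimated correlation), with Tsc22d3 2.29-fold lower. Of 10 neutrophil genes 3 rose (5 adjusted over the list alone; median 0.72, adjusted p = 9.51e-04, and adjusted p = 0.214 with an estimated correlation), with S100a8 2.97-fold higher (26.0 ± 3.12 against 8.73 ± 3.26 CPM). In males the mature migratory dendritic cell markers fell in 3 of 11 cases (4 adjusted over the list alone; median −0.30, adjusted p = 0.0266, and adjusted p = 0.465 with an estimated correlation). That list's call ended without male air library 3 or male smoke library 5 (adjusted p up to 0.199). Club cell markers were at a median of −0.41 (0 of 9 called, also adjusted over the list alone, adjusted p = 0.0486, and adjusted p = 0.746 with an estimated correlation). That call ended without male air library 1 or 2 or male smoke library 1 or 3 (up to 0.369). The club cell score was 9.26 in male air and 8.39 ± 1.49 in male smoke. Beside the neutrophil list, those of erythroid cells, platelets and megakaryocytes, B cells and plasma cells were also called in males. The erythroid score was 5.91 ± 1.12 in male air and 6.80 ± 0.0867 in male smoke.

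Lists that follow RNA quality or handling moved in males as well. Of 9 mitochondrially encoded genes 4 rose (6 adjusted over the list alone; median log2 fold change 0.43, adjusted p = 1.56e-04, and adjusted p = 0.435 with an estimated correlation). Of 15 cytosolic ribosomal protein genes 2 rose (7 adjusted over the list alone; median 0.16, adjusted p = 0.00429, and adjusted p = 0.697 with an estimated correlation), a call that ended without male air library 3 (adjusted p = 0.234). Of 14 immediate early genes, which respond within minutes to handling, 3 fell and 1 rose (7 fell and 1 rose adjusted over the list alone; median −0.73, adjusted p = 3.61e-04, and adjusted p = 0.465 with an estimated correlation), with Zfp36 lower and Ier3 higher. Of 11 heat shock genes 0 were called and 5 fell adjusted over the list alone (median −0.37, adjusted p = 0.0205, and adjusted p = 0.746 with an estimated correlation), a call that ended without male air library 3 or male smoke library 1 or 2 (adjusted p up to 0.812).

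For smoke in males 1678 genes passed the test, 806 higher and 872 lower in smoke, and 243 of them changed at least 2-fold. The largest rises were in Igkv3-4 (28.5-fold, adjusted p = 0.0274), Igj (10.2-fold), the neutrophil chemokine gene Cxcl5 (9.15-fold), Slc6a20a (6.75-fold), the chemokine gene Ccl8 (4.16-fold), the lipogenic gene Thrsp (4.06-fold), Gpr137c (3.87-fold) and Mrap (3.81-fold). Igkv3-4 ended without any 1 of the 3 air libraries (adjusted p up to 0.114), Igj without male air library 3 (0.0566) and Thrsp without air library 2 or 3 (up to 0.0956). Among the largest falls were those in Alb, Dbp (7.89-fold), Sprr1a (5.07-fold), Tnc, Zbtb16 (4.16-fold), Per1 and Hal (3.92-fold). Alb, the albumin gene of the liver, was at 104 ± 137 CPM in male air and 0.813 ± 0.345 CPM in male smoke. Its call ended without male air library 1 (adjusted p = 0.0623), the male library with the highest Alb level. In these tested genes 16.8% had groups that did not overlap, against 3.57% by chance. The count was 982 without male air library 3 and 1042 without male air library 2.

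**Figure D1:**
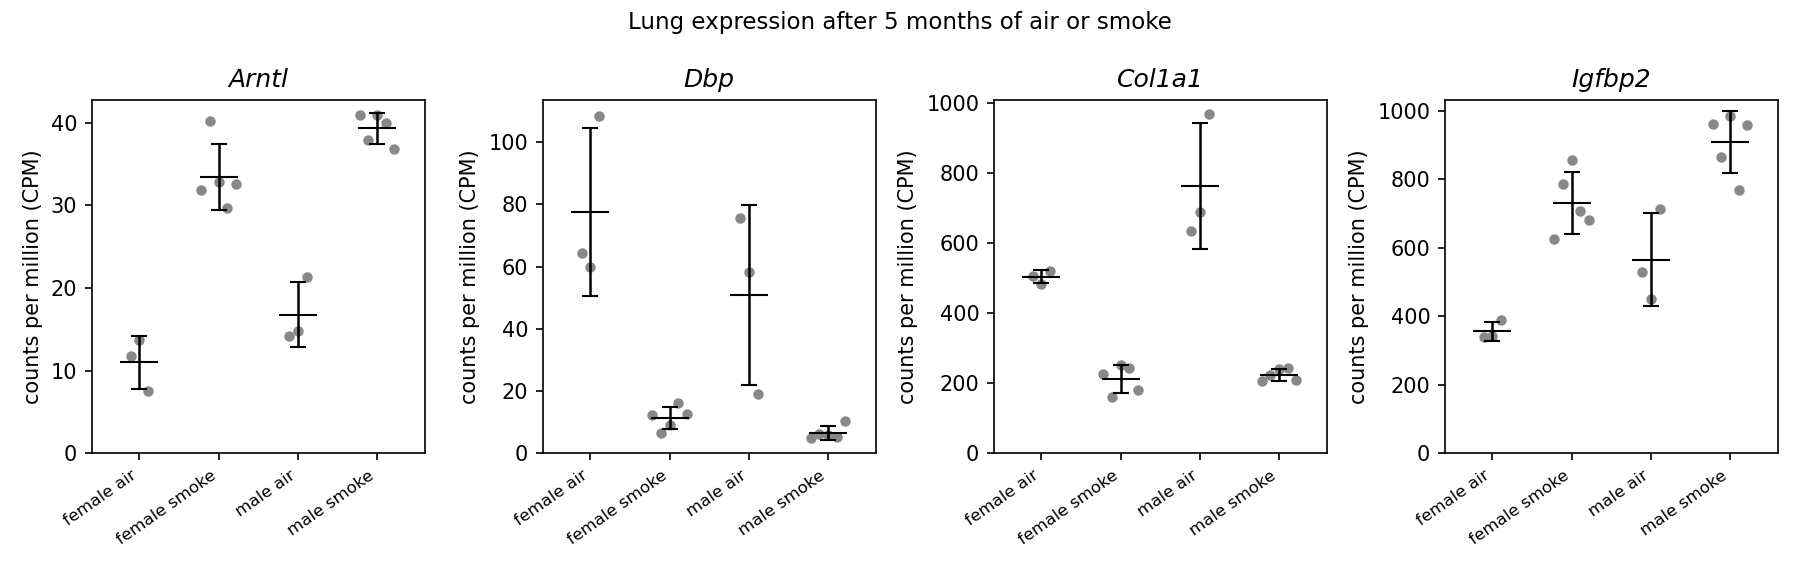
Level in CPM (y axis, from 0) of Arntl, Dbp, Col1a1 and Igfbp2 in female air (n = 3), female smoke (n = 5), male air (n = 3) and male smoke (n = 5). Gray points are libraries, black lines are group means and bars are SD; the Col1a1 means are 504 and 213 CPM in females and 765 and 224 CPM in males.

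Whether both sexes respond to smoke in the same genes was asked by their overlap and by the interaction of sex and smoke. Both sexes shared 717 called genes: 388 higher and 329 lower in smoke, where chance would give 36.4 and 27.7, and 0 went in opposite directions. Of the genes called in females, 96.5% had the same sign in males, against 68.9% of all genes, and the log2 fold changes of all genes correlated across genes with r = 0.649. Genes are not independent replicates, and the sexes share no libraries. Sample titles number the air libraries of both sexes in a run apart from the smoke libraries. A batch that follows this numbering would be common to both sexes and cannot be told apart from smoke. The overlap dropped to 338 without female air library 3. The interaction called 1 gene, Plcb1, a phospholipase C gene (chromosome 2, 134786159 to 135475258). It was at 18.7 ± 0.592 CPM in female air and 22.8 ± 3.60 in female smoke, but at 33.9 ± 4.25 in male air and 16.3 ± 2.52 in male smoke (difference of log2 fold changes 1.34, SE 0.19, adjusted p = 0.0128). This call ended without any 1 of the 3 female air libraries (adjusted p = 0.0835, 0.0553 and 0.0904) and without male air library 1 or 3 (0.0514 and 0.0552). At an unadjusted p under 0.05 there were 940 genes, DESeq2 called 17, and the replicate block and limma-trend on TPM each called 0, which ends the call of Plcb1. Ccl17 fell in females (log2 fold change −0.92) and was at −0.01 in males (SE 0.22), but the difference did not pass the test (−0.92, SE 0.31, adjusted p = 0.748).

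By lists, the smoke response of erythroid genes was larger in females (median difference 1.81 over 8 genes, 0 called and 7 adjusted over the list alone, adjusted p = 4.28e-07, and adjusted p = 0.847 with an estimated correlation). Their score in air was 4.59 in females and 5.91 in males, where male air library 3 stood at 7.19, and in smoke it was 7.003 and 6.80. Without male air library 3 the median difference dropped to 1.00. The fall of matrix genes was smaller in females (median difference 0.34, 0 of 15 called, also adjusted over the list alone, adjusted p = 0.00184, and adjusted p = 0.847 with an estimated correlation). That call ended without male air library 3 (adjusted p = 0.327).

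How the sexes differ without smoke was asked in 3 female and 3 male air libraries. The sex chromosomes separated them: Xist, the RNA that silences an X chromosome, was at 354 ± 85.6 CPM in females and 2.20 ± 1.55 in males, and Ddx3y, a Y-linked RNA helicase gene, at 0.120 ± 0.0241 and 81.2 ± 11.6 CPM. All 4 Y-linked genes were lower in females, also adjusted over the list alone (adjusted p = 2.62e-06 with an estimated correlation), and their fitted folds give no bound, since female levels were near 0. Of 6 genes that escape X inactivation 3 were higher in females (5 adjusted over the list alone, adjusted p = 1.03e-04 with an estimated correlation), including Kdm6a (1.63-fold). Among autosomal genes, the complement gene C3 was 1.87-fold lower in females (1616.3 ± 287 against 3017.8 ± 257 CPM, adjusted p = 0.00408, ended without female air library 3 with adjusted p = 0.0507), and the Wnt modulator gene Sfrp2 1.75-fold lower (24.8 ± 1.43 against 43.3 ± 5.66 CPM, adjusted p = 0.00207). Of 9 complement genes 1 was lower (5 adjusted over the list alone; median log2 fold change −0.31, adjusted p = 5.31e-05, and adjusted p = 0.203 with an estimated correlation). Matrix genes had a median of −0.40 (0 of 15 called and 8 adjusted over the list alone, adjusted p = 9.86e-08, and adjusted p = 0.401 with an estimated correlation). In all 12 lists were called, among them immediate early genes, which respond to handling, and erythroid, platelet, ciliated cell, mesothelium and B cell markers. Male air library 3 stood apart in erythroid score (7.19, others 5.38 and 5.16) and in Col1a1 (971 CPM, others 635 and 690).

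In air 29 genes passed the test, 8 higher and 21 lower in females, and 18 of them were autosomal. The other autosomal genes with the largest differences were Serpina3m (3.49-fold) and Plcb1 (1.81-fold), both lower in females, and Zfp692 (1.71-fold), P4ha2 (1.48-fold) and Sesn1 (1.43-fold), all higher. The calls of Serpina3m, Zfp692 and P4ha2 ended without any 1 of the 6 libraries (adjusted p up to 0.212, 0.137 and 0.224). Those of Sesn1 and Plcb1 ended without 5 of them (all but male air library 1 and all but male air library 2; up to 0.125 and 0.0878). The count was 19 and 15 without male air library 2 and 3, and 15, 10 and 11 without female air library 1, 2 and 3. Groups did not overlap for 16.7% of genes, against 10% by chance for 3 against 3 libraries.

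The sex difference after smoke was asked in 5 female and 5 male libraries. Serpina3m, a serine protease inhibitor gene (chromosome 12, 104338486 to 104394257), was 6.68-fold lower in females (1.11 ± 0.582 against 7.58 ± 1.34 CPM, log2 fold change −2.74, SE 0.29, adjusted p = 1.13e-05), and Serpina3n 1.67-fold lower. Itgbl1 (2.26-fold), Smoc2 (1.52-fold) and Wisp2 (1.46-fold) were also lower in females, while the matrix list did not pass the test (median −0.12, adjusted p = 0.0830). Oas2, an antiviral gene induced by interferon, was 2.26-fold higher in females (13.1 ± 3.50 against 5.83 ± 0.861 CPM, adjusted p = 0.00209). Of 21 type I interferon-stimulated genes 1 was higher (2 adjusted over the list alone), with 19 above 0 and a median log2 fold change of 0.30 (adjusted p = 1.15e-05, and adjusted p = 0.456 with an estimated correlation). The Y-linked genes (4 of 4 lower, also adjusted over the list alone) and those escaping X inactivation (5 of 6 higher, 6 adjusted over the list alone) again passed, with adjusted p = 1.12e-06 and 4.91e-06 with an estimated correlation.

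In smoke 31 genes passed the test, 9 higher and 22 lower in females, and 18 were autosomal. The other largest differences were Penk (2.21-fold lower), Olfm2 (1.78-fold lower), Prkg2 (1.45-fold lower), Zfp692 (1.52-fold higher) and Dkk3 (1.31-fold higher). Penk ended without any single library but female smoke 4 (adjusted p up to 0.134), and Prkg2 without female smoke library 1 (0.0549). Olfm2 ended without 7 libraries (male 2, 3 and 4, female 1, 2, 3 and 5; up to 0.134), Dkk3 without 7 (male 1, 3, 4 and 5, female 1, 3 and 4; up to 0.0961), and Zfp692 without male 4 or 5 or female 1 or 5 (up to 0.0839). Goblet cell genes had a median of 1.13 (0 of 8 called, also adjusted over the list alone, adjusted p = 1.58e-04, and adjusted p = 0.456 with an estimated correlation). Male libraries 4 and 5 and female libraries 1 and 5 had high airway scores, and the club cell score was 9.25 in females and 8.39 ± 1.49 in males. The count was 20 without female smoke library 1, and 1.60% of genes had groups that did not overlap, against 0.794% by chance. Air and smoke shared 15 sex-different genes (5 higher and 10 lower in females).

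Whether loss of the ovaries changes the smoke-exposed female lung at 3 months was asked in 3 ovariectomized and 3 sham libraries. Among clock genes, which did not pass the test one by one, Nfil3 was at 5.33 ± 1.26 CPM after ovariectomy and 14.6 ± 0.315 in sham, and Arntl at 19.7 ± 7.65 and 41.4 ± 1.24 CPM. Of 5 genes of the Bmal1 arm 0 were called over all genes and 5 were lower adjusted over the list alone (median log2 fold change −1.08, adjusted p = 6.30e-08, and adjusted p = 0.159 with an estimated correlation). Of the 10 of the Per and Dbp arm 0 were called and 7 were higher adjusted over the list alone (median 0.69, adjusted p = 4.07e-09, and adjusted p = 0.278 with an estimated correlation). Interferon-stimulated genes had a median of −0.24 (0 of 21 called, also adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.694 with an estimated correlation), a call that ended without sham library 1 or ovariectomized library 1 (adjusted p up to 0.291). T cell genes had a median of −0.44 (0 of 13 called, also adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.694 with an estimated correlation), a call that ended without sham library 1 or 3 or ovariectomized library 3 (up to 0.128). In all 9 lists were called, 0 of them with an estimated correlation. The others were alveolar type 1 cells, cardiac muscle, aryl hydrocarbon receptor targets, inflammatory cytokines and chemokines, and cytosolic ribosomal proteins, which follow RNA quality. The Alb level was over 100 CPM in ovariectomized libraries 2 and 3. edgeR called 0 of 16874 genes at 3 months, with 1568 at an unadjusted p under 0.05, and DESeq2 called 93. The edgeR count was 6 without ovariectomized library 1 and 1 without sham library 1. Groups did not overlap for 15.2% of genes, against 10% by chance.

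The same question at 5 months was asked in 5 ovariectomized and 5 sham libraries. Gdf10, a growth factor gene of the transforming growth factor beta family (chromosome 14, 33923587 to 33935280), rose 2.01-fold, from 8.21 ± 0.552 to 16.5 ± 2.67 CPM (log2 fold change 1.01, SE 0.14, adjusted p = 0.00305). Muc6, a gel-forming mucin gene (chromosome 7, 141633456 to 141655319), fell 4.98-fold, from 2.93 ± 0.867 to 0.589 ± 0.297 CPM (adjusted p = 0.0145). Oas2 fell 1.97-fold, from 11.3 ± 2.56 to 5.73 ± 1.24 CPM, a call that ended without sham library 1 or 3 or ovariectomized library 4 (adjusted p up to 0.0686). Igfbp2 rose 1.56-fold, from 928 ± 212 to 1446.6 ± 161 CPM, a call that ended without 8 libraries (all but sham library 2 and ovariectomized library 4; adjusted p up to 0.0938). The progesterone receptor gene Pgr, an estrogen target in reproductive tissue, was at 3.57 ± 1.05 after ovariectomy and 1.48 ± 0.717 CPM in sham but did not pass the test (log2 fold change 1.27, SE 0.34, adjusted p = 0.0598). The estrogen receptor gene Esr1 did not pass it either (log2 fold change 0.21, SE 0.18, adjusted p = 0.636).

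Among lists at 5 months, genes of the unfolded protein response, which refolds proteins in the endoplasmic reticulum, were lower, with 2 of 14 fallen (4 adjusted over the list alone; median log2 fold change −0.19, adjusted p = 5.12e-04, and adjusted p = 0.568 with an estimated correlation). Creld2 fell 1.34-fold, and Manf 1.36-fold, a call that ended without sham library 1 or ovariectomized library 1 (adjusted p up to 0.0627). Inflammatory cytokine and chemokine genes were all below 0, with 0 of 16 called and 2 lower adjusted over the list alone (median −0.50, adjusted p = 0.00325, and adjusted p = 0.325 with an estimated correlation). Of 5 genes of the Bmal1 arm 2 fell (4 adjusted over the list alone; median −0.88, adjusted p = 2.08e-04, and adjusted p = 0.325 with an estimated correlation), with Nfil3 1.84-fold lower, a call that ended without sham library 1, 3 or 5 or ovariectomized library 3 or 4 (adjusted p up to 0.113). Of the 10 of the Per and Dbp arm 2 rose (5 adjusted over the list alone; median 0.48, adjusted p = 2.08e-04, and adjusted p = 0.568 with an estimated correlation), with Tef 1.42-fold higher, a call that ended without ovariectomized library 3 (adjusted p = 0.0533). Alveolar type 1 genes rose in 2 of 11 cases (6 adjusted over the list alone; median 0.22, adjusted p = 5.30e-04, and adjusted p = 0.837 with an estimated correlation). Adventitial fibroblast genes rose in 1 of 9 cases (2 adjusted over the list alone; median 0.31, adjusted p = 2.08e-04, and adjusted p = 0.136 with an estimated correlation). Neutrophil genes had a median of −0.51 (0 of 10 called, also adjusted over the list alone, adjusted p = 0.0138, and adjusted p = 0.837 with an estimated correlation), a call that ended without sham library 5 or ovariectomized library 3 (adjusted p up to 0.0689). Mitochondrially encoded genes rose in 1 of 9 cases (4 adjusted over the list alone; median 0.28, adjusted p = 1.54e-04, and adjusted p = 0.568 with an estimated correlation) and cytosolic ribosomal protein genes in 1 of 15 (4 adjusted over the list alone; median 0.11, adjusted p = 2.08e-04, and adjusted p = 0.568 with an estimated correlation). The share of counts from Malat1, an RNA kept in the nucleus, was 0.154 ± 0.0280% after ovariectomy and 0.324 ± 0.0853% in sham (n = 5 each).

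At 5 months edgeR called 230 of 16874 genes, 99 higher and 131 lower after ovariectomy, and 16 changed at least 2-fold. For ovariectomy at 5 months DESeq2 called 602 genes, the fit of only both groups 143, and edgeR 100 without the libraries over 100 CPM of Alb. With a GC offset that also moves the level of each library, edgeR called 725, with 616 higher and 109 lower. Limma-trend on TPM, which changes the test, the unit and the scaling together, called 184, with 16 higher and 168 lower. So the balance of directions depends on the processing, and which step moves it was not tested. The largest rises were in Apol6 (2.71-fold, adjusted p = 0.0361), Gdf10, Fjx1 (1.91-fold), the water channel gene Aqp4 (1.86-fold), Scn3b (1.74-fold), the pericyte marker Rgs5 (1.71-fold), Ccdc122 (1.67-fold) and Srpx (1.64-fold). The largest falls were in Muc6, Fbxl12os (2.69-fold), Lrrc16b (2.18-fold), Pcsk4 (2.17-fold), Oas2, Erdr1 (1.92-fold), Nfil3 and Slco4a1 (1.82-fold). Erdr1 is a multicopy gene and Fbxl12os lies opposite another gene, so their counts are uncertain. The calls of Gdf10 and Muc6 held without each of the 10 libraries. The other 14 ended without 3 to 8 libraries each, always including sham library 1 (adjusted p up to between 0.0686 and 0.133). The count dropped to 39, 92, 98 and 82 without sham library 1, 3, 4 and 5, and to 71, 115 and 117 without ovariectomized library 1, 3 and 4. Groups did not overlap for 3.85% of genes, against 0.794% by chance.

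**Figure D2:**
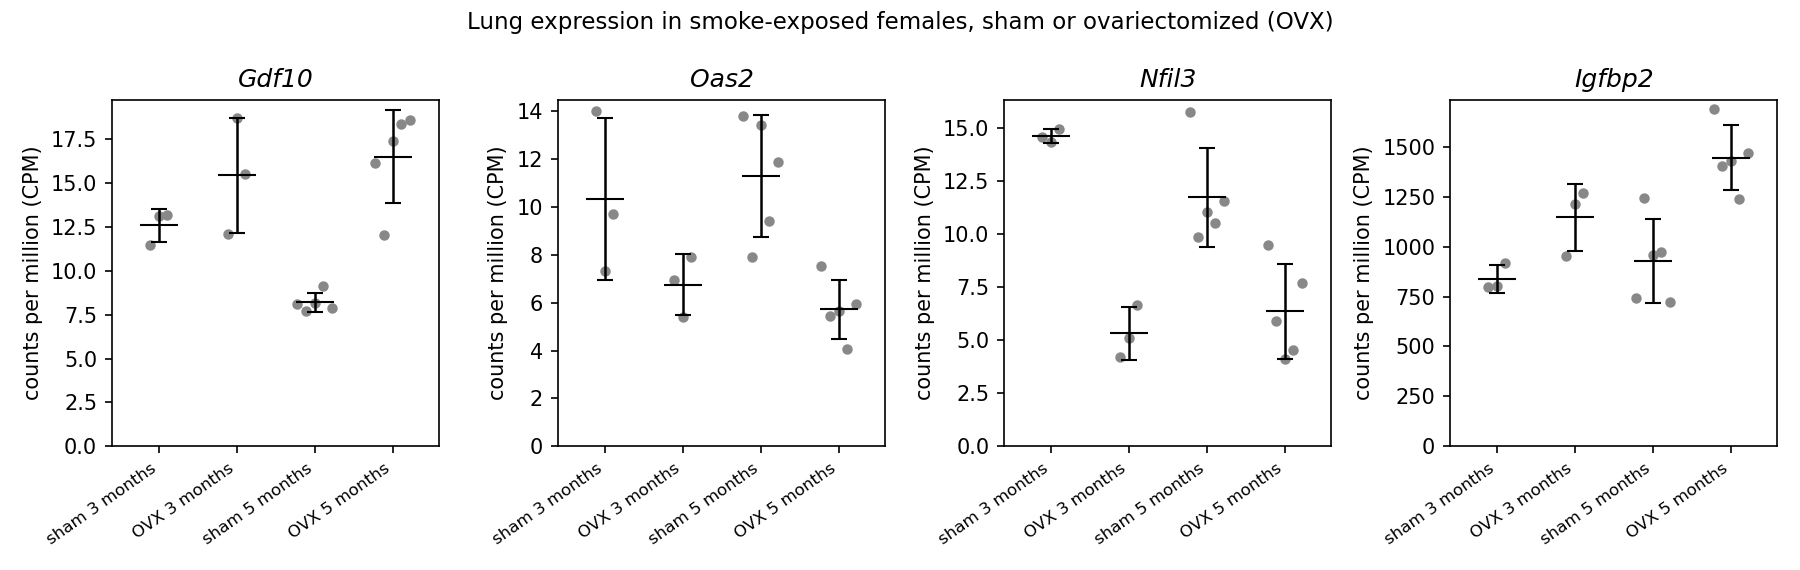
Level in CPM (y axis, from 0) of Gdf10, Oas2, Nfil3 and Igfbp2 in sham and ovariectomized smoke-exposed females at 3 months (n = 3 each) and 5 months (n = 5 each). Gray points are libraries, black lines are group means and bars are SD; at 5 months Gdf10 ranged from 7.68 to 9.13 CPM in sham and from 12.1 to 18.6 CPM after ovariectomy.

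Whether removing the ovaries moves the female lung toward the male pattern was asked with sets of 200 autosomal genes taken from the first experiment, which shares no libraries with the second. The sex sets come from sex in smoke, where chance is not excluded for the count of genes called (6 of 100 splits called as many, the real one included). Airway scores also varied between libraries of the same sex there, so these sets may hold more than a sex difference. The 200 male-high genes, of which 15 had passed the test between sexes, were higher after ovariectomy at 5 months, with 162 above 0 and a median log2 fold change of 0.159 (camera p = 6.25e-17, and p = 0.00167 with an estimated correlation). At 3 months 142 were above 0 and the median was 0.104 (p = 5.27e-04, and p = 0.121 with an estimated correlation), a call that ended without ovariectomized library 2 (p = 0.0559). With sets from sex in air the median of the male-high genes under ovariectomy at 3 months was 0.0478. Without the libraries over 100 CPM of Alb it was 0.0289, but this leaves only ovariectomized library 1 against 3 sham libraries. The 200 female-high genes, of which 3 had passed, were lower at 5 months, with 65 above 0 and a median of −0.108 (p = 8.15e-04, and p = 0.0314 with an estimated correlation). At 3 months their median was −0.105 (p = 0.0173, and p = 0.109 with an estimated correlation), a call that ended without ovariectomized library 2 (p = 0.149). All genes together had a median of −0.0125 at 5 months and 0.00348 at 3 months. Genes raised by smoke in females had a median of 0.0370 at 5 months (p = 0.0327, and p = 0.551 with an estimated correlation), and genes lowered by smoke one of 0.0939 (p = 6.32e-06, and p = 0.233 with an estimated correlation). Splits of the 5-month libraries gave as large a median in 7 of 100 for female-high, 49 for smoke-raised and 27 for smoke-lowered genes. So chance is not excluded for these 3 sets at 5 months. The call of the raised genes ended without sham library 1 or 5 or ovariectomized library 1 or 3 (p up to 0.353), with medians from 0.0137 to 0.0764 without single libraries. The sign turned on log2(TPM + 1), with −0.0222 for smoke-raised genes under ovariectomy at 5 months. At 3 months the raised genes had a median of 0.0849 (p = 0.0208, and p = 0.519 with an estimated correlation), a call that ended without sham library 2 or ovariectomized library 3 (p up to 0.397), and the lowered genes one of 0.0389 (p = 0.160). That of the smoke-lowered genes under ovariectomy at 3 months turned to −0.0186 without ovariectomized library 2 and to −0.0113 without the libraries over 100 CPM of Alb, where the ovariectomized arm is 1 library.

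Whether the effect of ovariectomy differs between 3 and 5 months was asked by their interaction and overlap. Of the 230 genes called at 5 months, 89.6% had the same sign at 3 months, against 60.7% of all genes, and 0 were called at both times, since edgeR called 0 at 3 months. Over all genes the log2 fold changes of both times had r = −0.0213 across genes, although 60.7% agreed in sign. So r alone does not show that the effects at both times are unrelated, and which genes set it was not tested. That overlap was 1 without ovariectomized library 1 of 3 months, and 26 with DESeq2. The interaction called 0 genes by edgeR, with 844 at an unadjusted p under 0.05, and DESeq2 called 23. Tested as sets, the effect on male-high genes was larger at 5 than at 3 months by a median of 0.0807 (camera p = 5.37e-05, and p = 0.0756 with an estimated correlation) and that on smoke-lowered genes by 0.0430 (camera p = 0.0165, and p = 0.517 with an estimated correlation), so neither passed with an estimated correlation. The differences of −0.0806 for the female-high and −0.0271 for the smoke-raised genes did not pass the test. Pericyte genes had a median difference of 0.37 (0 of 8 called and 1 adjusted over the list alone, adjusted p = 0.0306, and adjusted p = 0.982 with an estimated correlation), a call that ended without sham library 1 of 3 months or 3 of 5 months, or ovariectomized library 1 or 3 of 3 months or 3 or 5 of 5 months (adjusted p up to 0.150).

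Change from 3 to 5 months was asked within sham and within ovariectomized mice, where age, exposure and any batch go together. Gucy1b3 (chromosome 3, 82032004 to 82074711) fell in sham, from 62.4 ± 13.7 to 36.6 ± 5.52 CPM (log2 fold change −0.77, SE 0.12, adjusted p = 0.0240), and was the 1 gene called. The call ended without sham library 1 or 2 of 3 months or 2, 3 or 4 of 5 months (adjusted p up to 0.495). Pericyte genes fell in 1 of 8 cases (4 adjusted over the list alone; median −0.49, adjusted p = 7.79e-05, and adjusted p = 0.304 with an estimated correlation). Cholesterol synthesis genes had 18 of 18 above 0 in sham (0 called and 7 adjusted over the list alone; median 0.25, adjusted p = 1.76e-07, and adjusted p = 0.548 with an estimated correlation). In ovariectomized mice 16 of the 18 were above 0 (0 called and 3 adjusted over the list alone; median 0.24, adjusted p = 2.81e-05, and adjusted p = 0.893 with an estimated correlation). Cytosolic ribosomal protein genes, which follow RNA quality, and alveolar type 1 genes were also called as lists in both. In sham 17 lists were called, T cell, erythroid, platelet and endothelial ones among them, and in ovariectomized mice 3. By gene, 3 were called in ovariectomized mice: Cdk2ap1 fell from 37.6 ± 3.42 to 20.5 ± 3.38 CPM (adjusted p = 0.00303), Ccm2l from 31.0 ± 2.38 to 18.1 ± 1.49 (adjusted p = 0.00440) and Fbrsl1 from 51.1 ± 4.09 to 36.7 ± 2.27 (adjusted p = 0.0286). All 3 ended without ovariectomized library 1 of 3 months (Cdk2ap1 0.0932 and Ccm2l 0.0980), and Fbrsl1 also without libraries 2 and 3 of 3 months and 1, 2 and 3 of 5 months (up to 0.439). The count in sham was 0 without each of the 5 libraries named for Gucy1b3, 13 without sham library 3 of 3 months, and 2 and 14 without sham libraries 1 and 5 of 5 months. In ovariectomized mice it was 0 without library 1 of 3 months and 6 without library 5 of 5 months. At an unadjusted p under 0.05 there were 1459 and 1659 genes, and DESeq2 called 105 and 90. Groups did not overlap for 7.16% and 5.54% of genes, against 3.57% by chance.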

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

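Chosen after the results were seen were the 2 tests on GC content, the test of time of day for the clock genes, and the alternatives that leave out libraries rich in Alb or add GC offsets. By Dixon's test, 21 of 293 groups of 5 libraries tested held 1 library far from the other 4, and chance picks about 1 in 20 groups. Groups of 3 libraries were not screened. Among those, male air library 3 was at 19.2 CPM in Dbp (others 75.7 and 58.2) and at 5758 CPM in Hbb-bs (others 1996 and 2472). In CPM, female smoke library 4 stood out in Igkv4-59 (23.1; others 1.26 to 4.09), Slc4a1 (29.0; 6.89 to 13.2) and Alas2 (523; 169 to 257), and so did library 2 in Ighg2b (36.1; 1.96 to 9.08), Igj (241.6; 49.0 to 102), H2-Aa (663; 495 to 543) and Klf9 (123; 86.6 to 96.2). Female smoke library 1 stood out in Retnla (119; 44.4 to 63.1) and Gucy1b3 (60.5; 70.0 to 72.2), and library 3 in Angptl7 (11.4; 4.51 to 6.46) and Dkk3 (110.3; 90.2 to 94.9). Male smoke library 5 stood out in Dbp (10.2; 4.98 to 6.13), Per1 (47.8; 28.0 to 33.6) and Ednrb (58.8; 61.1 to 62.0), library 4 in Ccl8 (2.30; 3.64 to 4.07) and library 2 in Col3a1 (498; 459 to 467). At 5 months sham library 1 stood out in Nfil3 (15.8; 9.86 to 11.5) and in depth (14.2 M counts; 17.4 to 17.9), ovariectomized library 5 in Srpx (12.2; 7.56 to 8.88) and Alb (1107; 0.944 to 15.4), and library 2 in mt-Co1 (8931; 10936 to 11727).

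Tested differences between groups made up the rest. The response to smoke differed between sexes for Plcb1 (difference of log2 fold changes 1.34) and, as medians of lists, for erythroid cells (1.81), extracellular matrix (0.34), immediate early genes (0.39), mesothelium (0.21) and fatty acid synthesis (−0.15). With an estimated correlation none of these lists passed (adjusted p = 0.847 to 0.854). Immediate early genes ended without male air 3, female air 1, male smoke 1 or female smoke 5 (adjusted p up to 0.325), and the last pair of lists without 10 and 8 single libraries (up to 0.214 and 0.195). The effect of ovariectomy differed between 5 and 3 months for pericytes (0.37), arterial and venous endothelium (0.24), general capillary endothelium (0.17), the unfolded protein response (−0.26), the Per and Dbp arm of the clock (−0.36), male-high genes (0.0807) and smoke-lowered genes (0.0430), of which the latter pair did not pass with an estimated correlation (p = 0.0756 and 0.517 by camera). These 5 lists had an adjusted p of 0.982 with an estimated correlation, and each ended without 6 to 9 single libraries.

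The genes called after ovariectomy at 5 months were weighed against technical causes. Other splits of the 10 libraries called at most 8 genes where the real split called 230 (1 of 100 splits as large), so chance is excluded. A batch is not, since sample titles number the sham and ovariectomized libraries in separate runs. A batch that follows this numbering cannot be told apart from ovariectomy. GC content as the whole cause is argued against, since 181 of the 230 stayed called in the same direction with a GC offset, and the ratio of their fold changes was 0.969. A lower share of nuclear-retained RNA stays open, and the values tested go with it, so it may account for part of the pattern. Over the 22 libraries of the other 6 groups, the score of the called genes fell as Malat1 and Neat1 rose. The relation had r = −0.850 (permutation p = 5.00e-05, adjusted for 4 relations 2.00e-04), and −0.835 without the 2 farthest libraries. The nuclear RNA score was 10.6 ± 0.275 after ovariectomy and 11.4 ± 0.224 in sham. Every ovariectomized library also held fewer detected genes (17754 to 19754) than every sham library (19825 to 20418). Total counts were not lower after ovariectomy (14.8 to 24.5 M against 14.2 to 17.9 M). Whether this difference in genes detected adds to the calls was not tested. Clock phase also stays open, since its relation did not pass the test and was not bounded near 0 (r = 0.370, permutation p = 0.199), and so does the loss of the ovaries itself, which the design names and which was not tested apart from these.

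The rise of male-high genes after ovariectomy at 5 months was weighed next. The real median of 0.159 exceeded the other splits drawn (1 of 100 as large, highest other 0.125, 126 possible), so chance is argued against. That share is not adjusted for the 8 set medians tested, so it does not exclude chance. GC content is argued against, because with the offset the median was 0.163 (1.03 times the value without it). Nuclear-retained RNA stays open (r = −0.488 over the other groups, permutation p = 0.0750), and so does more adventitial fibroblast RNA (r = 0.217, permutation p = 0.375), since neither relation passed the test or was bounded near 0. A move of the female lung toward the male pattern on loss of the ovaries is the biological explanation the design names, and it may hold, but these tests do not part it from the open technical ones. A batch that goes with surgery stays open too. The set itself comes from sex in smoke, where chance is not excluded for the count of genes called.

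The clock genes between smoke and air were the last pattern. Liver RNA in some libraries is argued against: without the libraries over 100 CPM of Alb, the mean fitted log2 fold change of the Per and Dbp arm minus that of the Bmal1 arm was still −2.44 in females and −1.91 in males, against −2.30 and −2.17 with them (smaller ratio 0.879). Time of day of collection cannot be told apart from smoke, because both arms of the clock moved in opposite directions in both sexes, which a shift of phase and an effect of smoke would give alike, and the labels give no hour. Glucocorticoid targets and the counts of genes called between smoke and air were not tested apart from time of day either. After ovariectomy the clock score, normalised over all 32 libraries, moved the other way and was higher (2.13 against 0.195 at 3 months and 2.09 against 0.921 at 5 months), so the same caution holds there.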

How the results depend on the processing

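Chosen after the data were seen were the alternatives that leave out the libraries over 100 CPM of Alb and the centred and uncentred GC offsets; the others were planned. The 240 called genes named by the rule gave 4388 values over the alternatives, of which 3647 stayed called in the same direction, 741 were no longer called and 0 reversed. The 136 called lists gave 2690 values, of which 2241 stayed, 448 were lost and 1 reversed. Without single libraries, 117 genes, 70 lists, 3 of 8 sets and 1 of 12 counts kept their result in every case. Leaving out libraries rich in Alb ended 73 gene and 29 list calls, log2(TPM + 1) 51 and 7, the fit of all 32 libraries 33 and 8, the replicate block 33 and 5, no filter 24 and 5, the centred GC offset 18 and 5, the uncentred 24 and 13, and RLE factors 1 and 2. DESeq2 ended 0 of 237 gene calls and 9 list calls, and the strict filter 0 of 239 and 7. An estimated correlation ended 132 of the 136 list calls.

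DESeq2 called 93 genes for ovariectomy at 3 months, 602 at 5 months, 23 for ovariectomy by time, 26 shared between times, 17 for sex by smoke, 133 for sex in air, 63 for sex in smoke, 105 for time in sham and 90 in ovariectomized mice. In the pair of comparisons simulated with it, smoke in females and ovariectomy at 5 months, it also made more false calls than edgeR. Limma-trend on log2(TPM + 1) called 788 genes for smoke in females and 1022 for smoke in males, 378 for the overlap of smoke calls between sexes, 0 for sex by smoke, 15 for sex in air, 1 for ovariectomy at 3 months and 0 for time in sham. Its set medians at 3 months were −0.0694 for female-high (−0.101 with DESeq2) and 0.0258 for smoke-lowered genes, at 5 months −0.150 for female-high genes, and, reversed, −0.0222 for smoke-raised genes under ovariectomy at 5 months. Without a filter the counts were 3 for ovariectomy at 3 months, 2 shared between times, and 10 and 5 for time in sham and ovariectomized mice. The replicate block gave 10, 6, 18 and 9 for these, 0 for sex by smoke and 44 for sex in air. In 1 fit of all 32 libraries they were 6, 3 and 15 (time in sham), with 3 for sex by smoke and 47 for sex in air, and the smoke-lowered median at 3 months was 0.0608. Fits of only the 2 groups gave 2 and 143 genes for ovariectomy at 3 and 5 months and 0 for time in sham. The smoke-raised median at 5 months was 0.0373 with the strict filter and 0.0332 with the block.

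Leaving out the libraries rich in Alb leaves a single ovariectomized library at 3 months, assumed to vary like the other groups, so the values for ovariectomy at 3 months and for time in ovariectomized mice rest on it. Without the libraries rich in Alb, 401 genes were in the overlap of smoke calls between sexes, 100 were called after ovariectomy at 5 months and 2 for time in sham. This setting removes libraries and liver RNA together, so which of these moves the counts was not tested. The medians at 3 months were then −0.0526 (female-high), 0.0289 (male-high), 0.0143 (smoke-raised) and, reversed, −0.0113 (smoke-lowered genes under ovariectomy at 3 months). The GC offsets gave 4 genes each for time in sham. The uncentred form, which also moves each library's level, gave 725 genes for ovariectomy at 5 months (616 higher, 109 lower) and a smoke-raised median of 0.0935. With an estimated correlation the medians stay as they are by construction but calls ended for female-high (−0.105), male-high (0.104) and smoke-raised genes (0.0849) at 3 months and smoke-raised (0.0370) and smoke-lowered genes (0.0939) at 5 months. For male-high genes under ovariectomy at 3 months, sets from called genes and from sex in air had medians of 0.0873 and 0.0478. Apart from the estimated correlation, the cause of these changes was not tested.

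Leaving out 1 library at a time, counts ran from 459 to 1150 (smoke in females), 982 to 1693 (in males), 338 to 733 (shared), 0 to 4 (sex by smoke), 10 to 39 (sex in air), 20 to 31 (sex in smoke), 0 to 6 (ovariectomy at 3 months), 39 to 258 (at 5 months), 0 to 1 (shared between times), 0 to 0 (by time), 0 to 14 (time in sham) and 0 to 6 (in ovariectomized mice). Set medians at 3 and 5 months ran from −0.152 to −0.0857 and −0.155 to −0.117 (female-high), 0.0591 to 0.134 and 0.146 to 0.178 (male-high), 0.0499 to 0.117 and 0.0137 to 0.0764 (smoke-raised), and −0.0186 to 0.0688 and 0.0461 to 0.140 (smoke-lowered). The smoke-lowered set reversed at 3 months without ovariectomized library 2 (−0.0186), and B cells in sex in air, over −0.467 to −0.0319 without single libraries, ended and turned to the other direction in camera without female air library 3.

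The replicate numbers show little sign of pairing: deviations of same-numbered libraries correlated at −0.276 to 0.182, with 6 of 28 pairs over 0.1. For ovariectomy at 3 months 3 of 3 ovariectomized libraries correlated best with their own number, though only at 0.0308 to 0.0380. For smoke in females 3 of 5 smoke libraries did, and in each other comparison at most 1 library did. So a weak pairing is not excluded. Sets of called genes were not run for the female-high set, which has 3 called genes, and 3 and 1 genes have no value with DESeq2 and the strict filter. At this depth and number of libraries, edgeR recovered 38 to 52 of 100 simulated 1.5-fold changes in the smoke, sex in smoke and 5-month ovariectomy comparisons and 15 to 19 in the interactions, so many changes of that size are missed.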

Other observations

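The tests on other splits of libraries given here were all set before the results were seen; the list of liver genes below was chosen after. Smoke responses in either sex were far above other splits: 1259 genes in females (1 of 56 splits as large, highest other 62) and 1678 in males (1 of 56, highest other 126). So chance is excluded for these, but not a batch that goes with smoke in both sexes. For the 717 shared genes 1 of 100 splits was as large (highest other 0). Those splits mix smoke and air in both sexes at once and leave few calls to share. They therefore do not test the overlap apart from the calls of each sex. The share is also under 0.05 for the interaction of sex and smoke (1 gene; 4 of 100 splits as large; highest other 3) and for the lists called for sex in smoke (23 lists; 2 of 100 drawn of 126 possible; 23). There another split gave as many or more, so these counts do not stand above chance splits. For sex in smoke chance is not excluded for the count of 31 genes, where 6 of 100 splits were as large. Of these, 1 split called 509 genes, with male libraries 4 and 5 beside female libraries 1, 3 and 5. That points to a structure of the samples across the sexes, and 4 of these 5 libraries had high airway scores. The splits weigh only the count, not which genes are called. Only 18 of the 31 genes were autosomal, and Xist and the Y-linked genes separated the sexes. In the air libraries 5 of the 31 were also called higher and 10 lower in females, where chance would give 0.0044 and 0.0282. For change with time chance is not excluded in sham (1 gene; 5 of 56; 6) or ovariectomized mice (3 genes; 3 of 56; 56). For ovariectomy by time the real count is 0 (edgeR; 844 at an unadjusted p under 0.05 and 23 by DESeq2), so 100 of 100 splits are as large by construction and no share can be had; 1 of them called 54 genes.

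Among sets after ovariectomy at 5 months, chance is not excluded for the female-high (−0.108; 7 of 100 splits as large; highest other 0.163 in size), smoke-raised (0.0370; 49 of 100; 0.108) and smoke-lowered genes (0.0939; 27 of 100; 0.190). By number of lists called, it is not excluded for smoke in females (24; 5 of 56; 32), smoke in males (27; 3 of 56; 31), the interaction of sex and smoke (5; 93 of 100; 22), ovariectomy at 5 months (11; 29 of 100; 22), ovariectomy by time (5; 75 of 100; 22), or time in sham (17; 14 of 56; 24) and in ovariectomized mice (3; 45 of 56; 14). Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. They gave 29 genes (1 as large; highest other 0) and 12 lists (6; 18) for sex in air. For ovariectomy at 3 months they gave 0 genes by edgeR (10 by construction; 0; 1568 at an unadjusted p under 0.05 and 93 by DESeq2), 9 lists (5; 25), and medians of −0.105 for female-high (1; 0.0837 in size), 0.104 for male-high (1; 0.0975), 0.0849 for smoke-raised (2; 0.0967) and 0.0389 for smoke-lowered genes (9; 0.0944). For the overlap of ovariectomy calls between times, with 0 genes, no share can be had.

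Alb ranged from 0.530 to 1129 CPM over the 32 libraries and was over 100 CPM in 7: ovariectomized libraries 2 and 3 at 3 months, sham libraries 1 and 2 and ovariectomized library 5 at 5 months, male air library 1 and female air library 2. A list of 15 other liver genes, written after Alb was seen, followed it (Spearman rho 0.801). The share of counts from the mitochondrial genome was 1.65% in female air, 2.26% in female smoke, 1.79% in male air and 2.28% in male smoke, and at 5 months 2.03% in sham and 2.42% after ovariectomy. The share of Yam1 was 0.299 ± 0.151% after ovariectomy and 0.919 ± 0.513% in sham at 5 months.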
